A study of Mus musculus with 9 samples.

How the data were processed

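RNA from the midbrain (mesencephalon) of C57BL/6 mice was sequenced in 3 groups of 3 mice each: saline controls, mice given MPTP, and mice given MPTP with PF4. Per the labels, each library was made from 1 µg of total RNA with an mRNA library kit, and per the series design each group held 3 mice, so replicates were separate animals. The aligner, the counting program and the strand setting were not given in the sources used here; the submitters' processing notes name the genome build mm9.

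The authors deposited 1 table with whole-number read counts per gene and FPKM values per gene for every sample, per the file headers. The FPKM values in the deposited table were scaled by the authors for transcript length and library size, per the file headers. The same deposited table holds the authors' calls in words (up or down) for each pair of groups, made with DESeq2 at a p of 0.05 and a 2-fold change per the file headers; the authors' p and fold columns were not used here, and whether that p was adjusted was not given in the sources used here. Of 29001 lines, 10 lines with broken annotation fields were left out, which left 28991 genes: 22036 with Ensembl identifiers and 6955 loci without a known gene, which held 0.98% to 1.22% of the counts of a library. Gene symbols came from the deposited table. For gene positions, lengths and GC content, 22022 identifiers matched the GENCODE annotation of the GRCm38 build, which is not the build named in the labels; no position was converted.

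Total counts ranged from 32216850 to 36039211 per library, and 16303 to 16889 genes had at least 10 counts. At this depth 3 counts correspond to 0.0832 to 0.0931 CPM (the count scaled to the library total), the level below which a transcript could not be told from 0 in 1 library. This covers counting error only. No 2 libraries agreed within sampling noise: the lowest chi-square per degree of freedom between libraries was 32.6.

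Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, robust estimation, TMM factors, filterByExpr, all 9 samples in 1 fit on the group), with Benjamini-Hochberg adjustment over the 17285 genes that passed the filter and an adjusted p under 0.05 as the threshold. Fold changes are log2 with their standard error (SE), and CPM values use the TMM-scaled library totals. Gene lists for midbrain cell types, pathways and neighbouring tissues were fixed before the data were examined; 47 of 49 had at least 3 tested members. They were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over all lists of a comparison. Fry stands for its directional test, except where its mixed test, which ignores direction, is named. The planned test of annotation terms needed at least 20 genes past the threshold in 1 direction and was not run, since no gene passed. For the dopaminergic genes and Pf4, CPM values were also compared with an exact two-sided permutation test, whose smallest possible p with 3 samples against 3 is 0.1.

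The genes named in the text follow a rule fixed before the data were examined: Th, Slc6a3, Slc18a2, Ddc and Pf4 always; the genes with the largest fold changes among those past the threshold; for each list past the camera threshold the 2 to 4 members with the smallest p; where fewer than 5 genes passed, the 5 with the smallest unadjusted p; and genes past the threshold in opposite directions in both treated comparisons. For most lists the text prints only some of the members that the rule gives, not always those with the smallest p. The regional genes given per library were chosen after their values were seen, unless a fixed list holds them.

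The fits were tested on simulated counts for MPTP against control, drawn with the means, totals and dispersions of these libraries, with 200 genes changed by 2-fold or 4-fold. The draws varied each gene on its own and held no structure shared by libraries, so their false calls do not measure those in the data. At the spread of these libraries edgeR, on 17024 genes past its filter, recovered 3% of the 2-fold and 67% of the 4-fold changes with 2 false calls. DESeq2 1.42.0, on 17285 genes, recovered 27% and 83% with 44 false calls. Limma voom with sample weights, on 17024 genes, recovered 4% and 64% with 0 false calls. At a dispersion of 0.02 edgeR, on 17042 genes, recovered 97% and 100% with 10 false calls. With a GC trend added to 2 libraries at that dispersion, edgeR made 532 false calls on 17066 genes, and 9 on 15275 genes after the GC and length correction. The common biological coefficient of variation of these libraries was 0.394.

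Alternatives fixed before the data were examined were: size factors by relative log expression, library totals alone, DESeq2 with its default independent filtering, limma voom with sample weights, no low-count filter, at least 1 CPM in 3 samples, the 6 samples of a comparison alone, robust estimation off, the replicate number as a block, 1 surrogate variable from sva 3.50.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5, a 1.5-fold minimum, each replicate left out, and library totals without mitochondrial and haemoglobin genes. Fold changes from FPKM are on the log2(FPKM + pseudocount) scale, which understates changes of low genes. Chosen after seeing the data were: leaving out control 1 and MPTP+PF4 2 together, leaving out controls 2 and 3 and MPTP+PF4 2 together, the striatal list as a covariate, a per-library correction for GC content and transcript length (alone and without control 1), DESeq2 with filtering tuned to 0.05, and DESeq2 at an unadjusted p under 0.05 with a 2-fold change, the threshold the file headers name.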

Results

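The transcriptome of the mouse midbrain was measured in 9 libraries, 3 each from saline controls, from mice injected with MPTP for 7 days, and from mice given MPTP and an intravenous injection of PF4 every 3 days. MPTP is a toxin whose metabolite enters dopaminergic neurons through the dopamine transporter. PF4 (platelet factor 4) is a chemokine released by platelets. Library totals lay between 32216850 and 36039211 counts. Mitochondrially encoded transcripts took 9.14% to 14.2% of the counts, and haemoglobin transcripts took 0.628% in control 2 against 0.0053% to 0.0792% in the other libraries.

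The dopaminergic genes were examined first, since they check the treatment. Slc6a3, the dopamine transporter (chromosome 13, 73536747 to 73578672, GRCm38), was at 574 CPM in control 2 and 526 CPM in control 3, but at 0.393 CPM in control 1. In the MPTP libraries it was at 0.055, 0.958 and 0.122 CPM, and in the MPTP+PF4 libraries at 0.338, 102 and 0.402 CPM. Th, tyrosine hydroxylase (chromosome 7, 142892752 to 142931128), was also highest in controls 2 and 3 and MPTP+PF4 2, with 7.49, 195 and 176 CPM in controls 1 to 3, 5.58 to 18.1 CPM with MPTP, and 4.95, 51.7 and 7.10 CPM with MPTP+PF4. Slc18a2, the vesicular monoamine transporter (chromosome 19, 59260896 to 59296012), and Ddc, the enzyme that forms dopamine (chromosome 11, 11814101 to 11898144), were at 14.6 and 16.2 CPM in control 1 and at 259 and 185 CPM in control 3. The transcript of Pf4 itself (chromosome 5, 90772435 to 90773383) was at 0.154 to 2.53 CPM across all libraries; the injected protein does not add to it.

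Genes of striatal projection neurons ran the other way. Drd1, a dopamine receptor, was at 4.04 and 4.80 CPM in controls 2 and 3 and at 7.74 CPM in MPTP+PF4 2, against 44.5 to 398 CPM in the other 6 libraries, control 1 included at 158 CPM. Adora2a, an adenosine receptor, was at 1.32 to 2.78 CPM in those 3 libraries and at 25.3 to 302 CPM in the other 6. The midbrain transcription factor En1, itself in the dopaminergic list, was at 7.23, 13.7 and 3.78 CPM in controls 2 and 3 and MPTP+PF4 2, and at 0 to 0.183 CPM in the others. Outside that list, Gata3 was at 11.3, 7.28 and 1.52 CPM in those libraries and 0 to 0.091 CPM in the others. Tal1 was at 11.1, 13.2 and 4.90 CPM against 0.962 to 1.45 CPM. The serotonergic and GABAergic lists that hold Gata3 and Tal1 did not pass by camera in any comparison. The first principal component, with 54.3% of the variance, placed controls 2 and 3 and MPTP+PF4 2 on 1 side (128.5, 88.0 and 33.0) and the other 6 libraries on the other (−74.0 to −6.33). Control 1 correlated with the 3 MPTP libraries at 0.971 to 0.977 across genes, and with controls 2 and 3 at 0.898 and 0.933; genes are not independent replicates.

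**Figure D1:**
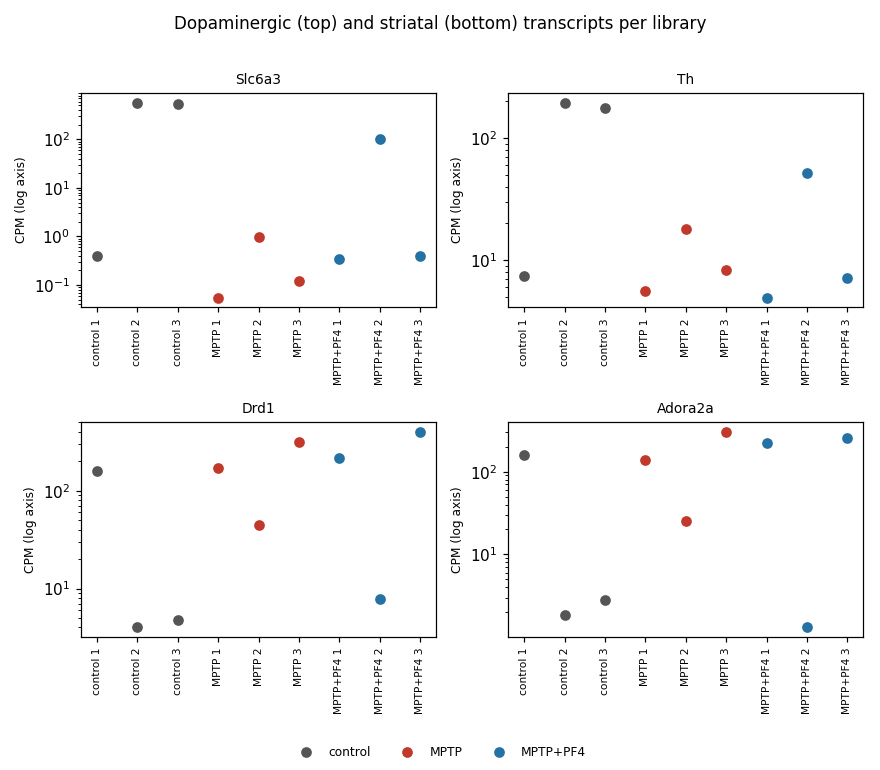
CPM on a log axis of Slc6a3 and Th (dopaminergic) and of Drd1 and Adora2a (striatal) in each of the 9 libraries, 1 point per library, coloured by group. Slc6a3 lies at 574, 526 and 102 CPM in controls 2 and 3 and MPTP+PF4 2 and under 1 CPM in the other 6, in which Drd1 is at 44.5 CPM or more.

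MPTP against control asked what differed with the toxin. Controls 2 and 3 also differed from control 1 and the MPTP libraries in regional transcripts, so these differences need not be effects of the toxin. In edgeR no single gene passed the threshold, and the dopaminergic genes had large but uneven differences: Slc6a3 was at 367 ± 318 CPM in controls and 0.378 ± 0.503 CPM with MPTP (SD, n = 3 each), a log2 fold change of −9.89 (SE 3.16), and Th had −3.56 (SE 1.25). The smallest p-values belonged to other genes. Il33, an alarmin cytokine, was at 124 ± 7.57 CPM in controls and 60.6 ± 3.95 CPM with MPTP (SD, n = 3 each; log2 fold change −1.03, SE 0.148). Serpinb1a, a protease inhibitor, had −1.69 (SE 0.228), Tsc22d3, a glucocorticoid-induced gene, −1.15 (SE 0.175), Serpind1, heparin cofactor II, −2.41 (SE 0.396), and Chrdl1, a BMP antagonist, 2.77 (SE 0.479); in each the groups did not overlap.

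In edgeR, 0 of 17285 genes passed (smallest adjusted p 0.261), while 3154 had an unadjusted p under 0.05, 920 higher and 2234 lower, where chance gives 864. DESeq2 called 289 genes (51 higher, 238 lower), and limma voom with sample weights 8887. The authors' deposited table lists 314 higher and 864 lower; of these 1178 calls 235 were among the DESeq2 calls at an adjusted p, and 1086 among 1629 at an unadjusted p under 0.05 and 2-fold, an alternative chosen after seeing the data. The groups did not overlap for 18.2% of genes, where chance gives 10%. Without control 1, edgeR called 4577 genes (2104 higher, 2473 lower); without control 1 and MPTP+PF4 2, an alternative chosen after seeing the data, it called 5629. The exact two-sided permutation test gave p = 0.2 for Slc6a3 and Ddc, 0.3 for Th and Pf4 and 0.4 for Slc18a2.

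By camera, 17 of 47 lists passed, 12 lower and 5 higher, and none passed with an estimated correlation (smallest adjusted p = 0.675 with an estimated correlation) or with fry (smallest adjusted p 0.317). In none of these lists did a member pass in edgeR over all genes tested. Fry's mixed test gave adjusted p = 0.0339 for the glucocorticoid response list and for the cerebellar neuron list, which was not among the 17. The dopaminergic neuron list was lower, with a median log2 fold change of −3.33 over 22 members (adjusted p = 2.06e-05, and adjusted p = 0.675 with an estimated correlation). Of its members 14 fell when adjusted over the list alone, against 0 over all genes; Aldh1a1, a retinal dehydrogenase, had −2.49 (SE 0.602) and Gch1, which makes the cofactor of tyrosine hydroxylase, −2.97 (SE 0.906). The striatal neuron list was higher in the same comparison, with a median of 1.61 over 10 members (adjusted p = 0.013, and adjusted p = 0.675 with an estimated correlation); 0 members passed when adjusted over the list alone, and Penk had 1.65 (SE 1.26). With 1 surrogate variable the dopaminergic call ended, at a median of 0.00, and the striatal list turned to −0.78. That variable was 0.653, 0.449 and 0.17 in controls 2 and 3 and MPTP+PF4 2, and −0.385 to −0.027 in the other libraries. Fitting it removes this contrast, so the surrogate fit cannot test it. With controls 2 and 3 and MPTP+PF4 2 left out, chosen after seeing the data, the medians of both lists were 0.20 and 0.12.

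Cytosolic ribosomal protein genes were lower, with a median of −1.05 over 76 members, 75 of them below 0 (adjusted p = 3.74e-16, and adjusted p = 0.675 with an estimated correlation). The median was −0.40 with a correction for GC content and length and −0.52 with the striatal list as covariate, both chosen after seeing the data. Of the members 63 fell when adjusted over the list alone, among them Rps24 (−1.47, SE 0.393) and Rps15 (−1.57, SE 0.422). The nuclear oxidative phosphorylation list had a median of −0.70 over 75 members (adjusted p = 8.12e-11, and adjusted p = 0.675 with an estimated correlation), and 32 fell when adjusted over the list alone, with Uqcrq of complex III at −1.51 (SE 0.424) and Ndufs6 of complex I at −1.50 (SE 0.428). Within the controls, the mean log2 CPM of the ribosomal list was 6.92 in control 1, 8.52 in control 2 and 7.99 in control 3, and it was 6.81 to 7.06 in the MPTP libraries. That of the oxidative phosphorylation list was 6.44 in control 1, 7.53 in control 2 and 6.91 in control 3, and 6.24 to 6.44 in the MPTP libraries.

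Myelin genes were lower in all 18 members of the mature oligodendrocyte list, with a median of −0.84 (adjusted p = 9.88e-07, and adjusted p = 0.675 with an estimated correlation). Of these 11 fell when adjusted over the list alone, among them Mog, a protein of the outer myelin surface, at 196 ± 24.1 CPM in controls and 78.8 ± 27.5 CPM with MPTP (SD, n = 3 each), Opalin (−1.30, SE 0.300) and Cnp (−1.05, SE 0.274). Glucocorticoid response genes had a median of −0.36 over 17 members (adjusted p = 0.0133, and adjusted p = 0.675 with an estimated correlation); 6 fell when adjusted over the list alone, with the metallothionein Mt2 at −1.57 (SE 0.410) and the lipid droplet gene Plin4 at −1.68 (SE 0.454). Cholesterol synthesis genes had a median of −0.33 over 19 members (adjusted p = 0.013, and adjusted p = 0.675 with an estimated correlation), and 4 fell when adjusted over the list alone, with Mvd at −1.32 (SE 0.352) and Msmo1 at −0.74 (SE 0.203).

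Vessel and meningeal lists were lower as well: endothelial cell (median −0.50, Ly6c1 −1.02, SE 0.256), pericyte and smooth muscle (median −0.78, Myh11 −1.64, SE 0.496) and meningeal fibroblast (median −1.50, Lum −1.44, SE 0.446), with adjusted p = 0.00223, 0.00509 and 0.00524, and adjusted p = 0.675 with an estimated correlation for each. Adjusted over the list alone, 1, 4 and 0 of their 14, 12 and 12 members fell. Control 2 was the highest control in each, with a mean log2 CPM of 5.70 against 5.12 and 5.22 for endothelial (MPTP 4.67 to 4.98), 5.06 against 3.89 and 4.12 for pericyte (MPTP 3.44 to 3.78) and 4.39 against 2.16 and 1.86 for meningeal fibroblast (MPTP 1.44 to 2.21). The erythrocyte list had a median of −5.45 over 6 members (adjusted p = 0.000619, and adjusted p = 0.675 with an estimated correlation), and 5 fell when adjusted over the list alone; Hbb-bs was at 2079 CPM in control 2, 78.4 and 231 CPM in controls 1 and 3 and 16.1 to 19.6 CPM with MPTP. MHC class I (median −0.61, H2-K1 −1.54, SE 0.499) and lysosome and autophagy genes (median −0.33, Npc2 −1.12, SE 0.333) were lower with adjusted p = 0.0179 and 0.0292, and adjusted p = 0.702 and 0.675 with an estimated correlation, and 0 members of either passed when adjusted over the list alone. Reads of the haemoglobin and MHC class I genes can be shared between near-identical copies, so values of single members are uncertain.

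Higher lists were ependymal cell (median 1.31 over 10 members, Rsph1 of motile cilia 1.15, SE 0.376), circadian clock (median 0.46, Nr1d1 0.86, SE 0.281), glutamatergic neuron and synapse (median 0.48, Gria2 0.98, SE 0.451) and proliferation and neurogenesis (median 0.56). Their adjusted p were 0.000975, 0.00636, 0.0292 and 0.0274, each with adjusted p = 0.675 with an estimated correlation; 0 members of the first 3 passed when adjusted over the list alone. In the last list Eomes, a transcription factor of forebrain progenitors and unipolar brush cells, passed when adjusted over the list alone, at 10.6, 3.07 and 0.852 CPM with MPTP and 0 to 0.168 CPM in controls. Control 1 stood apart from controls 2 and 3 in 3 of these lists: its mean log2 CPM was 5.72 against 4.96 and 5.16 for circadian clock (MPTP 5.47 to 6.08), 1.92 against 0.46 and −0.21 for ependymal (MPTP 1.46 to 3.23), and 2.27 against 1.18 and 1.31 for proliferation (MPTP 1.83 to 3.10). In the glutamatergic list control 2 was lowest, at 6.32, against 7.37 and 7.05 in controls 1 and 3 and 6.93 to 7.68 with MPTP.

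Several of these list calls ended when 1 library was left out. Without control 1 they were MHC class I (median −0.81), glucocorticoid response (−0.36), lysosome and autophagy (−0.44) and cholesterol synthesis (−0.40). Without control 2 they were glutamatergic (0.34), MHC class I (−0.34), meningeal fibroblast (−0.14) and lysosome and autophagy (−0.14), and without control 3 striatal (1.08) and proliferation (0.45). Without MPTP 1 they were glutamatergic (0.47) and proliferation (0.22), without MPTP 2 MHC class I (−0.51), glucocorticoid response (−0.19) and lysosome and autophagy (−0.27), and without MPTP 3 glutamatergic (0.53), striatal (0.77), circadian clock (0.35) and cholesterol synthesis (−0.17). With controls 2 and 3 and MPTP+PF4 2 left out the ribosomal call ended too, at 0.027. With 1 surrogate variable, which takes out the contrast between those libraries and the others, the glutamatergic, MHC class I and circadian clock calls ended. Their camera direction turned, at −0.011, −0.040 and −0.058.

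**Figure D2:**
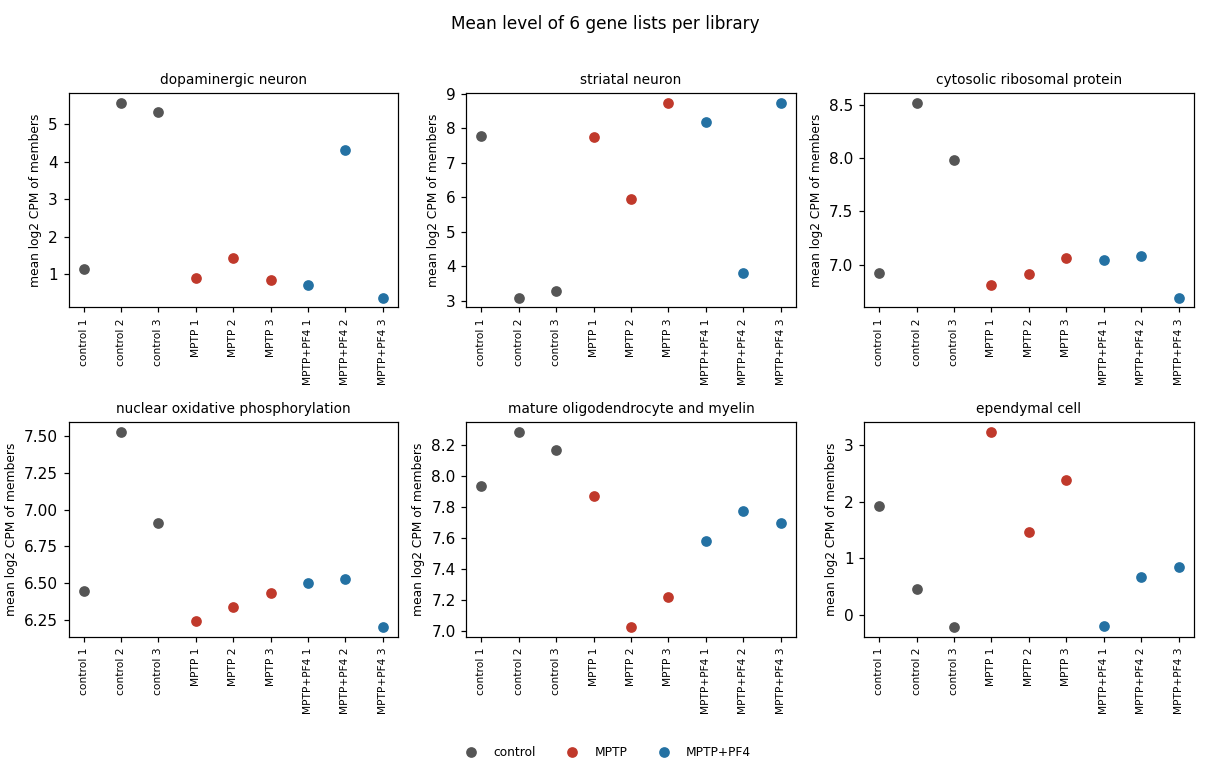
Mean log2 CPM of the members of 6 gene lists in each of the 9 libraries, 1 point per library, coloured by group. The dopaminergic and ribosomal lists are highest in controls 2 and 3, and control 1 lies with the MPTP libraries in both.

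MPTP+PF4 against MPTP asked what PF4 changed in mice given the toxin. Again no single gene passed in edgeR. Il33 was at 111 ± 14.0 CPM with PF4 and 60.6 ± 3.95 CPM without it (SD, n = 3 each), a log2 fold change of 0.87 (SE 0.148), and was higher in 3 of 3 libraries. Dnah10, a dynein heavy chain of motile cilia, had −2.48 (SE 0.373) and Lrrc23, also of motile cilia, −2.16 (SE 0.420). The urea transporter Slc14a2 had −2.88 (SE 0.512) and the transcription factor Zic1 −2.07 (SE 0.408), with 170 ± 75.8 CPM with MPTP and 40.5 ± 8.36 CPM with MPTP+PF4 (SD, n = 3 each). Slc6a3 had 6.47 (SE 2.80), and Th 1.00 (SE 1.15); without MPTP+PF4 2, which held 102 CPM of Slc6a3, these were −0.05 and −0.82.

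In edgeR, 0 of 17285 genes passed (smallest adjusted p 1), and 347 had an unadjusted p under 0.05, 112 higher and 235 lower, where chance gives 864. DESeq2 called 17 genes (3 higher, 14 lower), and limma voom with sample weights 13. The authors' deposited table lists 30 higher and 176 lower, 13 of which were among the DESeq2 calls at an adjusted p and 165 among 359 at an unadjusted p under 0.05 and 2-fold. The groups did not overlap for 7.12% of genes, where chance gives 10%. Leaving out control 1 and MPTP+PF4 2 left the count at 0. The exact two-sided permutation test gave p = 0.5 for Slc6a3 and Ddc, 0.9 for Th and Slc18a2 and 1 for Pf4.

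By camera, 15 lists passed, 11 higher and 4 lower, and 24 passed without MPTP+PF4 3; none passed with an estimated correlation (smallest adjusted p = 0.682 with an estimated correlation) or with fry (smallest adjusted p 0.992). The ependymal cell list was lower, with a median of −2.14 over 10 members (adjusted p = 2.1e-16, and adjusted p = 0.682 with an estimated correlation). Of these 7 fell when adjusted over the list alone, against 0 over all genes, with Rsph1 at −1.54 (SE 0.381) and Cfap126 at −1.94 (SE 0.515). The choroid plexus list had a median of −2.71 over 12 members (adjusted p = 0.000503, and adjusted p = 0.809 with an estimated correlation), 0 of which passed when adjusted over the list alone, with Slc4a5 at −4.24 (SE 1.83); without MPTP 1, which held 18.1 CPM of Slc4a5, it was 0.16, and the list's median was −0.22 with its call ended. Ttr, the main choroid plexus transcript, was at 2923 CPM in MPTP 1, 32.7 and 62.7 CPM in MPTP 2 and 3 and 27.6 to 111 CPM with MPTP+PF4, and at 945 CPM in control 1. The cerebellar neuron list was called lower (adjusted p = 0.00378, and adjusted p = 0.682 with an estimated correlation) though its median was 0.11 and its mean −0.59 (median −1.60 without MPTP+PF4 2); 4 members fell when adjusted over the list alone, the developmental transcription factors Zic1, Zic2, Zic4 and Eomes. Eomes also belongs to the proliferation and neurogenesis list, which was lower with a median of −0.36 (adjusted p = 0.00378, and adjusted p = 0.797 with an estimated correlation).

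Of the glial lists, microglia identity, mature oligodendrocyte and astrocyte identity were higher, and oligodendrocyte precursor (median −0.0025, adjusted p = 0.918), reactive astrocyte (−0.04, adjusted p = 0.114) and disease-associated microglia (0.16, adjusted p = 0.164) did not pass. All 20 microglia identity genes were above 0, with a median of 0.42 (adjusted p = 4.46e-07, and adjusted p = 0.685 with an estimated correlation). Of these, 0 passed when adjusted over the list alone. Siglech, the member with the smallest p, had 0.57 (SE 0.296), and the fractalkine receptor Cx3cr1 had 0.34 (SE 0.252). The mature oligodendrocyte list had a median of 0.26 over 18 members (adjusted p = 5.47e-06, and adjusted p = 0.785 with an estimated correlation), with Mog at 0.81 (SE 0.255), and the astrocyte list 0.24 over 15 members (adjusted p = 0.00445, and adjusted p = 0.682 with an estimated correlation), with Aldh1l1 at 0.56 (SE 0.201). Cholesterol synthesis genes were above 0 in all 19 members, with a median of 0.26 (adjusted p = 1.44e-06, and adjusted p = 0.682 with an estimated correlation) and Msmo1 at 0.60 (SE 0.203). Glucocorticoid response genes had a median of 0.23 (adjusted p = 0.000782, and adjusted p = 0.682 with an estimated correlation), with Tsc22d3 at 0.61 (SE 0.173), and immediate early genes 0.33 (adjusted p = 0.00839, and adjusted p = 0.873 with an estimated correlation), with Fos at 0.60 (SE 0.229).

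The 13 mitochondrially encoded genes were all above 0, with a median of 0.45 (adjusted p = 8.15e-09, and adjusted p = 0.682 with an estimated correlation) and mt-Nd6 at 0.52 (SE 0.243); their share of counts was 9.40%, 9.14% and 12.3% with MPTP and 14.2%, 10.6% and 13.8% with MPTP+PF4. The erythrocyte list had a median of 2.02 over 6 members (adjusted p = 0.000317, and adjusted p = 0.685 with an estimated correlation). Meningeal fibroblast, endothelial cell and pericyte lists had medians of 0.60, 0.18 and 0.27 (adjusted p = 0.0108, 0.0159 and 0.0301, and adjusted p = 0.914, 0.809 and 0.873 with an estimated correlation). In the microglia identity, mature oligodendrocyte, astrocyte identity, mitochondrial, vessel, meningeal, erythrocyte, cholesterol, glucocorticoid and immediate early lists 0 members passed when adjusted over the list alone.

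Calls that ended with 1 library left out were, besides choroid plexus, proliferation without MPTP 1 (median −0.09). Without MPTP 2 they were oligodendrocyte (0.04), endothelial (0.06), pericyte (0.14), meningeal fibroblast (0.59), cerebellar (0.13), immediate early (0.04) and glucocorticoid response (0.06), and without MPTP 3 meningeal fibroblast (0.45). Without MPTP+PF4 1 they were pericyte (0.29) and immediate early (0.19), without MPTP+PF4 2 astrocyte (0.11), endothelial (0.15), pericyte (0.17), meningeal fibroblast (0.21) and proliferation (−0.18), and without MPTP+PF4 3 immediate early (0.15).

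**Figure D3:**
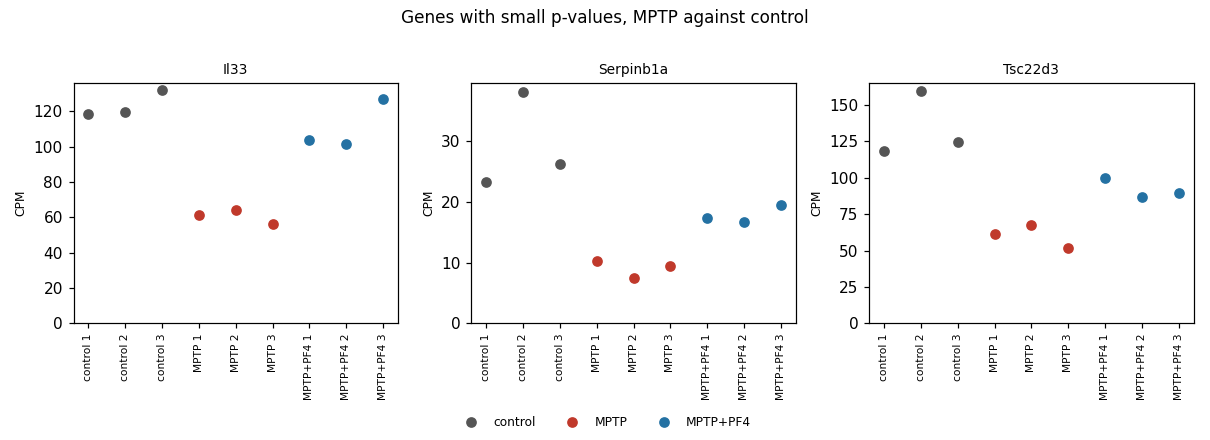
CPM of Il33, Serpinb1a and Tsc22d3 in each of the 9 libraries, 1 point per library, coloured by group, with the axes starting at 0. Il33 lies at 56.3 to 64.1 CPM in the MPTP libraries and at 101 CPM or more in the other 6.

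MPTP+PF4 against control asked whether mice given both differed from saline mice. No single gene passed in edgeR. Chrdl1, the BMP antagonist, had the smallest p, at 1.31 ± 0.642 CPM in controls and 10.8 ± 3.43 CPM with MPTP+PF4 (SD, n = 3 each; log2 fold change 3.04, SE 0.484). Rpl17, a ribosomal protein, had −1.39 (SE 0.281), and Pvalb, a calcium-binding protein of fast-spiking neurons, −1.95 (SE 0.429), at 217 ± 140 CPM in controls and 56.4 ± 10.2 CPM with MPTP+PF4 (SD, n = 3 each). The unnamed locus NewGene_5002 had −4.06 (SE 0.849). AC144408.3, at 0.342 ± 0.165 CPM in controls (SD, n = 3), had no counts in the 3 MPTP+PF4 libraries, where 3 counts would be 0.0892 to 0.0931 CPM.

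In edgeR, 0 of 17285 genes passed (smallest adjusted p 0.268), and 3171 had an unadjusted p under 0.05, 1080 higher and 2091 lower, where chance gives 864. DESeq2 called 9 genes (4 higher, 5 lower), and limma voom with sample weights 9347. The authors' deposited table lists 242 higher and 700 lower, 7 of which were among the DESeq2 calls at an adjusted p and 892 among 1405 at an unadjusted p under 0.05 and 2-fold. The groups did not overlap for 12.4% of genes, where chance gives 10%. Without control 1, edgeR called 4539 genes (2194 higher, 2345 lower), and without control 1 and MPTP+PF4 2 it called 5980. The exact two-sided permutation test gave p = 0.2 for Th, 0.3 for Slc6a3, Slc18a2 and Ddc and 0.5 for Pf4.

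By camera, 9 lists passed, 5 lower and 4 higher; 18 passed without control 3 and 14 without MPTP+PF4 2. None passed with an estimated correlation, where the adjusted p = 0.854 with an estimated correlation for each of the 9, or with fry (smallest adjusted p 0.5). Ribosomal protein genes had a median of −1.01 over 76 members (adjusted p = 2.15e-16), and 61 fell when adjusted over the list alone, against 0 over all genes, among them Rps15 (−1.58, SE 0.422). The nuclear oxidative phosphorylation list had a median of −0.63 (adjusted p = 2e-08) with Uqcrq at −1.56 (SE 0.425), and the dopaminergic list −1.86 (adjusted p = 0.00136) with Slc10a4 at −1.42 (SE 0.463) and the transcription factor Pitx3 at −4.09 (SE 1.69); 0 members of either passed when adjusted over the list alone. MHC class I genes had a median of −0.76 (adjusted p = 0.00136) with the peptide-loading gene Tapbp at −0.96 (SE 0.315), and mature oligodendrocyte genes −0.49 (adjusted p = 0.00435) with Gal3st1 at −0.69 (SE 0.242). Higher were circadian clock (median 0.42, adjusted p = 0.00612, Clock 0.65, SE 0.236), immediate early (median 0.70, adjusted p = 0.00832, Npas4 1.26, SE 0.429, but Ier2 −1.47, SE 0.487), glutamatergic (median 0.53, adjusted p = 0.0206, Gria3 0.91, SE 0.383) and microglia identity genes (median 0.37, adjusted p = 0.0343, P2ry12 1.55, SE 0.578). P2ry12 was at 43.5 CPM in control 1 and at 11.5 and 10.5 CPM in controls 2 and 3. Calls that ended with 1 library left out were microglia identity without control 1 (0.43), control 3 (0.22) or MPTP+PF4 1 (0.27), glutamatergic without control 2 (0.31) or MPTP+PF4 1 (0.45), and immediate early without MPTP+PF4 1 (0.59). The dopaminergic call ended with 1 surrogate variable, where the list's median turned to 0.39. That variable takes out the contrast of controls 2 and 3 and MPTP+PF4 2 with the other libraries, so its fit cannot test it. With those libraries left out, the dopaminergic and ribosomal medians were −0.31 and −0.02.

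Genes that changed with MPTP and changed the other way with PF4 were counted next. In edgeR 0 genes passed in both comparisons with opposite sign; DESeq2 gave 9 and limma voom with sample weights 12. Across genes, which are not independent replicates, both fold changes correlated at −0.47, where 20 draws with no effect gave −0.50 on average (−0.54 to −0.46), since both use the same MPTP libraries. The covariance was −0.21 against −0.17 in the draws (−0.18 to −0.16), and 54.7% of genes had opposite signs against 66.6%. The draws varied each gene on its own and held no regional difference between libraries, so they cannot tell treatment from region. With 3 MPTP libraries they could not be divided into parts of at least 2, so part of any excess may come from the shared libraries.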

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

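Alternatives chosen after seeing the data are named as added; the others were fixed before. The counts of changed genes depended on the tool and on control 1, and the list calls on the assumed correlation; the cause was not tested except where stated. For MPTP against control, MPTP+PF4 against MPTP and MPTP+PF4 against control, edgeR gave 0 genes each, DESeq2 289, 17 and 9, DESeq2 with filtering tuned to 0.05 (added after seeing the data) 279, 17 and 9, DESeq2 at an unadjusted p under 0.05 and 2-fold (added; a looser threshold) 1629, 359 and 1405, and limma voom with sample weights 8887, 13 and 9347, with weights of 0.202, 0.439 and 5.26 for controls 1 to 3. Opposite changes numbered 0 in edgeR, 9 in DESeq2 at either filtering, 169 at the unadjusted p and 12 in voom. DESeq2 made 44 false calls and limma voom 0 in the simulated comparison at this spread. Those draws held no structure shared by libraries, so these numbers do not measure false calls in the data. With each replicate left out, MPTP against control ranged from 0 to 4577 genes and MPTP+PF4 against control from 0 to 4539, both highest without control 1 and 0 without any other library; of the 4577 genes 4538 had the same sign with all libraries. Also added after seeing the data: without control 1 and MPTP+PF4 2 both comparisons gave 5629 and 5980 genes; without controls 2 and 3 and MPTP+PF4 2, where the lone control was assumed to vary like the other groups, 1 and 1; with the GC and length correction and without control 1, 3362 and 2525. Both sets of libraries were picked by their regional transcripts, so these counts describe how far the result rests on them and are no tests of treatment. MPTP+PF4 against MPTP stayed at 0 in these fits. In each remaining alternative edgeR or limma gave 0 genes in all comparisons.

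Lists past the camera threshold numbered 17, 15 and 9, and 0, 0 and 0 with an estimated correlation or with fry. Limma voom with sample weights gave 11 in MPTP against control, as did the striatal list as covariate (11, added); without controls 2 and 3 and MPTP+PF4 2, MPTP+PF4 against control gave 15. With a replicate left out, the counts ranged from 12 to 24 in MPTP+PF4 against MPTP (highest without MPTP+PF4 3) and from 7 to 18 in MPTP+PF4 against control (18 without control 3, 14 without MPTP+PF4 2). The camera direction of 7 list calls turned. With 1 surrogate variable these were, in MPTP against control, the striatal (median −0.78), glutamatergic (−0.011), MHC class I (−0.040) and circadian clock lists (−0.058), and in MPTP+PF4 against control the dopaminergic list (0.39). Without controls 2 and 3 and MPTP+PF4 2 they were the striatal (0.12) and ribosomal lists (0.027) in MPTP against control. The surrogate variable separated those libraries from the others, so its fit removes that contrast and cannot test it. Among named genes and lists, 5290 values under the alternatives kept their direction in the test and their side of the threshold, and 592 newly passed. Since no gene passed in the main fit, genes among the 5290 stayed short of the threshold, so this count is no measure of robustness. A further 119 values no longer passed, among them the dopaminergic neuron list in MPTP against control with 1 surrogate variable, at 0.00. That list's median was 0.20 without controls 2 and 3 and MPTP+PF4 2. Another 42 values of genes turned sign with neither value past the threshold.

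Replicate numbers were not taken to pair the samples, since not every same-numbered pair had correlated deviations over 0.1: 6 of 9 did (median 0.158, lowest −0.291, the 3 pairs of replicate 2 at 0.174 to 0.519), against 5 of 18 other-numbered pairs (median −0.11). The replicate block gave 0 genes in each comparison and 19, 17 and 10 lists. Depth, at 32216850 counts or more, limited genes near 0.0832 to 0.0931 CPM, the level of 3 counts.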

Other observations

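The tests of explanations below were chosen after the results they bear on were seen; the counts of other splits were the exception.

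Transcripts of other regions marked single libraries. The hypothalamic peptides Pmch and Hcrt were at 490.5 and 62.8 CPM in MPTP+PF4 2, while Pmch was at 48.7 CPM in control 1 and at 0.055 to 3.56 CPM in the other 7. Avp and Oxt, peptides of magnocellular neurons, were at 43.6 and 29.3 CPM in MPTP 2 and at no more than 4.96 and 1.77 CPM elsewhere. The glutamate transporter Slc17a7 ranged from 9.28 CPM in MPTP 2 to 524 CPM in control 3, and Slc17a6 from 27.7 CPM in MPTP 3 to 373 CPM in MPTP+PF4 2. Cd74, an MHC class II chaperone, was at 36.3 CPM in control 2, the library richest in haemoglobin transcripts, and at 2.58 to 5.13 CPM elsewhere.

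Low dopaminergic with high striatal transcripts appeared in all 3 MPTP libraries, in control 1 and in MPTP+PF4 1 and 3. No MPTP library had Slc6a3 at the level of controls 2 and 3, the highest being at 0.958 CPM. This argues against a swap only if the swapped control held the same region as controls 2 and 3. A control with low Slc6a3 would go unseen among the MPTP libraries, so such a swap stays open. No test covered an exchange with an MPTP+PF4 library, and MPTP+PF4 2 had Slc6a3 at 102 CPM, against 574 and 526 CPM in controls 2 and 3. Such an exchange stays open. Control 1, at 0.393 CPM, counts against MPTP as the whole cause only if its saline label is right; a single wrong label stays open, so MPTP is not excluded there. A different dissected region is a candidate explanation that stays open: the lowest striatal list mean of those 6 libraries lay 2.15 above the highest of the other 3 on the log2 scale, but this restates the pattern and does not test it. Within the MPTP libraries toxin and region cannot be told apart, since the controls themselves held both levels of the striatal list. Its mean log2 CPM was 7.79 in control 1, 3.10 and 3.28 in controls 2 and 3, and 5.96 to 8.74 with MPTP. The list's median log2 fold change of 1.61 lay under the SD of 2.66 between controls, but these are on different scales. That SD also comes mostly from control 1, so setting them side by side decides nothing.

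Ribosomal protein genes were lower with MPTP, with a median of −1.05. GC content and length differed between libraries. Spearman rho across genes with GC was 0.422 and 0.438 in controls 2 and 3 and −0.521 to −0.131 in the other libraries. A correction for GC content and length left a median of −0.40, with an interquartile range over members of 0.348. Camera then gave adjusted p = 5.76e-07 at the preset correlation, and adjusted p = 0.725 with an estimated correlation. With the striatal list as covariate the median was −0.52, with an interquartile range of 0.275. Camera then gave adjusted p = 2.03e-10, and adjusted p = 0.823 with an estimated correlation. That covariate separates controls 2 and 3 and MPTP+PF4 2 from the other libraries (3.10 to 3.81 against 5.96 to 8.74). It therefore also takes out differences between them that are not regional. With those libraries left out the median was 0.027, so the lower level rests on controls 2 and 3. A high ribosomal mean log2 CPM, 8.52 and 7.99, occurred only in controls 2 and 3, the libraries with a positive rho. MPTP+PF4 2 was at 7.08 though its striatal mean was 3.81, against 6.69 to 7.06 in the libraries with high striatal means. It did not follow region, and control 1, at 6.92, did not follow its saline label, but each is 1 library. Each adjustment removed about as much as it left or more. GC content and length bias, regional difference and treatment therefore cannot be told apart here, and each may contribute.

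Il33, Serpinb1a and Tsc22d3 were lower, and Dnah10 and Lrrc23 of motile cilia higher, in each MPTP library than in all 6 others. Genes that set those 3 libraries apart by at least 1.5-fold numbered 332 (203 higher, 129 lower), but 15 of the 84 splits of 3 against 6 libraries gave as many, with 2995 for controls 2 and 3 and MPTP+PF4 2, so chance was not excluded and the splits point to a structure of the samples. A lower share of mature oligodendrocytes is a candidate explanation for part of the set, which holds Mog; the oligodendrocyte list's lowest other library lay below the highest MPTP library (−0.293 on the log2 scale) because of MPTP 1 alone, which decides nothing. A higher share of ependymal cells is a candidate explanation for part of the higher genes; the ependymal list's lowest MPTP library lay below the highest other library, control 1 (−0.46), because of MPTP 2 alone, which decides nothing either. A response to MPTP that PF4 offsets stays open. The fold changes with MPTP and with PF4 correlated at −0.47, within the −0.54 to −0.46 of draws with no effect. Their covariance of −0.21 lay outside the −0.18 to −0.16 of the draws, on the side of an offset. Opposite signs went the other way, at 54.7% of genes against 66% to 67.1% in the draws. The draws varied each gene on its own, without the regional differences between these libraries, so their ranges decide nothing about PF4.

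Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For MPTP against control the real split gave 3154 genes at an unadjusted p under 0.05 and the highest other 4347 (2 splits as many or more, the real one included); for lists, 17 and 23 (4 splits). For MPTP+PF4 against MPTP these were 347 and 2103 (5 splits), and 15 and 18 (6 splits). For MPTP+PF4 against control they were 3171 and 6581 (2 splits), and 9 and 23 (8 splits). The split with 6581 set control 1 with MPTP+PF4 1 and 3 against controls 2 and 3 and MPTP+PF4 2 and called 1811 genes by edgeR's adjusted p, where the real split called 0, which points to a structure of the samples other than the treatment.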
